A study of Mus musculus with 6 samples.

How the data were processed

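RNA was measured in 6 libraries of CT26.WT cells, a mouse colon carcinoma line, 3 from control cells and 3 from treated cells. The groups and the library numbers 1 to 3 come from the sample titles. Per the labels' protocols, mRNA was selected from total RNA with oligo-dT beads, the second cDNA strand was marked with dUTP and removed, and paired reads were made on an Illumina NovaSeq instrument. Nothing in the labels says that the libraries of a group come from separate cultures, so p-values measure only the spread between these samples, which may be technical.

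Per the file headers, the authors deposited an FPKM value (fragments scaled to transcript length and library size) and a count for each gene and library, with gene identifiers, coordinates and annotation terms. The counts are estimated counts: the authors deposited them as whole numbers, their ratio to FPKM was constant for a gene across libraries (median coefficient of variation 0.0397% over 9955 rows), and low values were too frequent at multiples of 4. A count of 4 occurred 4054 times, against a mean of 2539.5 for the counts on either side, and a count of 8 occurred 1989 times, against 1420. Each sequenced fragment therefore seemed to weigh about 4 estimated counts. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without their roles or order. The genome build, the annotation release and whether the counting used the strand are not given in the sources used here. Coordinates are printed as the authors' file gives them. Genes that overlap another gene, antisense genes, near-identical copies such as Hspa1a and Hspa1b, and processed pseudogenes of ribosomal proteins are uncertain for this reason.

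Totals were 71409968 to 81821380 estimated counts in control libraries and 62328377 to 70323604 in treated libraries. Divided by 4, they are closer to the number of fragments. The floor used for a gene at 0 in a group was 3 fragments, or 12 estimated counts, per library, and it covers counting error only. No column of per-sample values was left unused.

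The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited estimated counts, which were already whole numbers, after edgeR's default filter on low counts and TMM scaling, 2-sided, with Benjamini-Hochberg adjustment over the 16212 rows tested of 25407 and a threshold of 0.05 on the adjusted p. The design, written before the data were examined, named a limma fit on log2(FPKM + 1) for rows with a mean FPKM of at least 1 as the main test, and the edgeR test in its place if the file held counts. The limma fit (limma 3.58.1) became an alternative. Fold changes are log2, treated over control. Their standard error (SE) was derived from the test, as the absolute fold change over the square root of the F statistic. Group values are mean FPKM ± SD with n = 3. A group is summarised by 48 gene lists, all fixed before the data were examined, from general knowledge and not from these samples. A list with at least 5 tested members was tested with camera, which compares its genes with all other tested genes, at a preset correlation between genes of 0.01, with adjustment over 43 lists. Camera with an estimated correlation and fry were alternatives. GO and KEGG terms from the authors' file were tested with a 1-sided Fisher exact test against the 13176 tested genes with any term, for terms of 15 to 500 genes, with adjustment over 5148 tests.

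Genes named in the text follow a rule fixed before the data were examined. It takes the 10 raised and the 10 lowered genes with the largest fold change among those past the threshold with no overlap between groups, leaving out predicted genes, pseudogenes and clone names. It takes up to 4 members past the threshold with the smallest p in each list, and its most abundant member that did not pass. It takes 20 genes whatever their result, up to 3 members with the smallest p in each term described, and the most abundant gene of each group. Other named genes are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

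GC content and transcript length came from GENCODE M21 transcripts, matched on gene identifier for 97.2% of tested rows. A GC correction with a loess fit per library (span 0.4) was added after a trend with GC was seen. Other alternatives were DESeq2 1.42.0, other scalings, filters and pseudocounts, a replicate block, each library left out in turn, and, chosen after the data were seen, protein-coding genes only, library totals only, counts divided by 4, and the libraries numbered 2 left out. The edgeR step was tested on simulated data for treated against control, with counts drawn from the real means for 15920 genes. It recovered 80% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, and called 4 unchanged genes. With a simulated GC trend and the correction, 69% and 99% were recovered among 15491 genes, and 10 unchanged genes were called; without the correction, 31% and 99% were recovered among 15917 genes and 18 unchanged genes were called. In these runs the changed genes were drawn only from genes with higher mean counts, and all genes had the same spread between libraries. Far fewer genes changed than in the data, and the weight of about 4 counts per fragment was not simulated. These rates therefore do not cover genes with low counts and may not hold for these libraries. Camera called a simulated shifted list and 0 of 42 lists of unchanged genes. The simulated genes were drawn independently and the lists at random, so this run cannot test the preset correlation on correlated genes. In the data the estimated correlation of the immediate early genes, for example, was 0.388.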

Results

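Gene expression was compared between 3 control and 3 treated libraries of CT26.WT cells, a mouse colon carcinoma line used in studies of tumour immunity. The treated cells had received Cu2O@AuMn@HA, a nanoparticle with copper oxide, gold and manganese parts, together with NaHS, a donor of hydrogen sulfide, and near-infrared light. Doses, exposure times and the time of harvest are not given in the sources used here. The series title names hydrogen sulfide consumption, heating by light, ferroptosis (an iron-dependent form of cell death) and immunotherapy as its subjects, and the comparison asks how the combined treatment changed the transcriptome. Totals were 71409968 to 81821380 estimated counts in control and 62328377 to 70323604 in treated libraries. Of 25407 gene rows, 18681 to 18970 were above 0 in control libraries and 20621 to 21059 in treated libraries. The first principal component carried 57.1% of the variance and separated the groups. Ribosomal RNA took 3.77% ± 0.162 (SD, n = 3) of estimated counts in control and 0.222% ± 0.0120 in treated libraries. Genes of the mitochondrial chromosome took 1.51% ± 0.315 and 2.54% ± 0.794.

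In treated cells, hypoxia-linked genes were higher as a group, and genes of DNA replication, mitosis, ribosome biogenesis and the ATF4 amino acid response were lower. The hypoxia, mitotic and ATF4 calls were lost with an estimated correlation (camera adjusted p = 0.0912, 0.0912 and 0.249). The metallothionein genes Mt1 and Mt2 and the heat shock genes Hspb1, Hspa1a and Hspa1b rose, while the heat shock list as a whole was not called. The small heat shock protein Hspb1 rose from 0.0792 ± 0.0875 to 7.71 ± 1.17 FPKM (mean ± SD, n = 3), a log2 fold change of 6.40 ± 0.57 (SE), or 7.60 without control 2. The mitophagy receptor Bnip3 rose from 12.7 ± 1.5 to 114 ± 16.1 FPKM (log2 fold change 3.12 ± 0.11). Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, fell from 49.2 ± 1.30 to 15.5 ± 0.422 FPKM (log2 fold change −1.71 ± 0.06). Asns, asparagine synthetase, fell from 200.01 ± 3.26 to 66.3 ± 0.618 FPKM (log2 fold change −1.63 ± 0.07). Of 16212 rows tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 7548 (46.6%) changed, 3735 rising and 3813 falling, and 2440 changed at least 2-fold, 1600 of them upward. The balance of directions depended on the fit: with library totals only 4183 rose and 3351 fell, and in limma on genes with a mean FPKM of at least 5, 309 rose and 317 fell by at least 2-fold. Camera called 16 of 43 gene lists, 9 higher and 7 lower, of which the S phase and ribosome biogenesis lists were also called with an estimated correlation. With the GC correction and an estimated correlation the S phase call was lost (adjusted p = 0.0623), and the ribosome biogenesis, mitotic, and autophagy and lysosome lists were called (0.0459 each). Fold changes fell with the GC content of transcripts (Spearman −0.28 across 10080 genes, which are not independent replicates), and with a GC correction 7889 of 15760 rows changed (4194 rising, 3695 falling), 6339 of them shared with the uncorrected fit in the same direction.

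**Figure D1:**
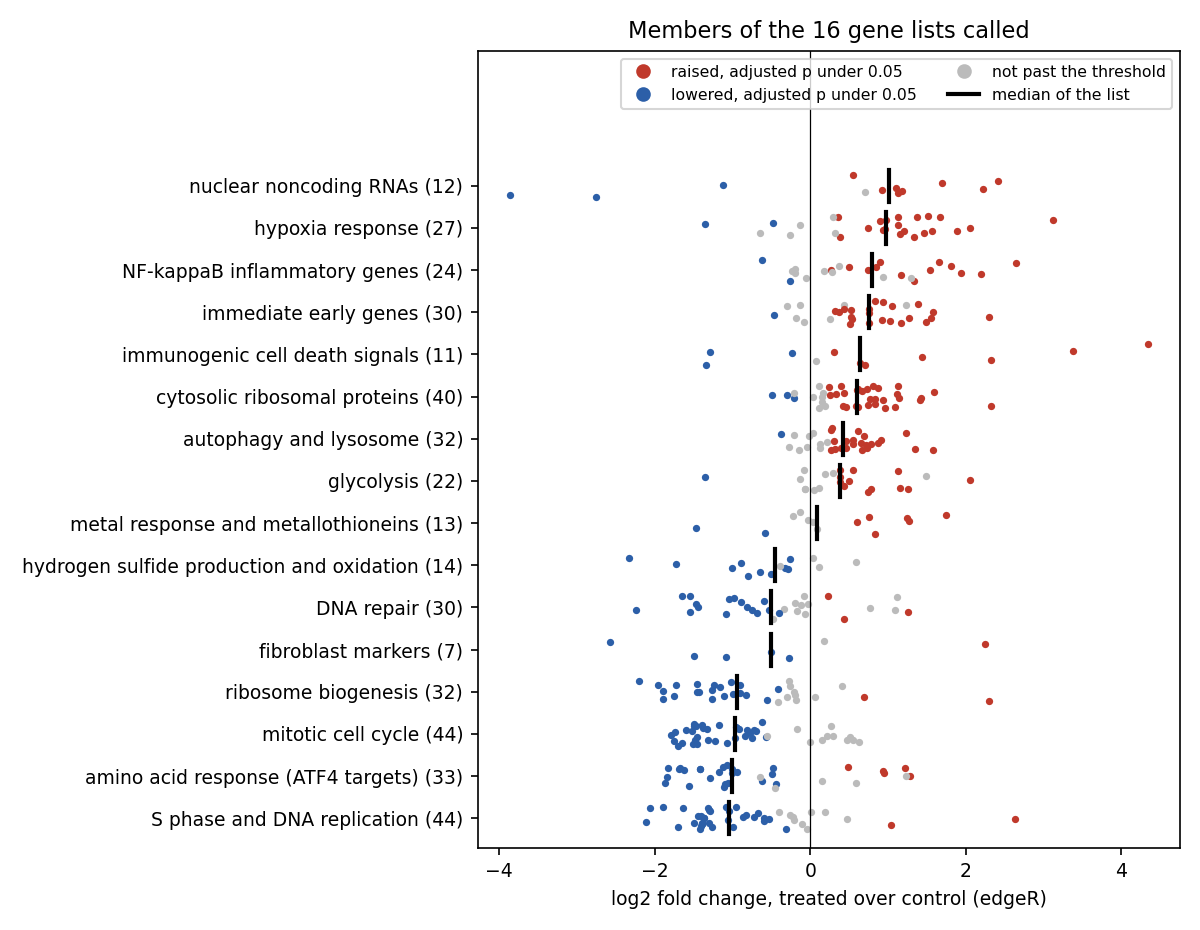
Log2 fold changes, treated over control (horizontal axis), of every tested member of the 16 gene lists called by camera, with the number of tested members after each name. Red and blue points passed an adjusted p of 0.05 in edgeR's test, grey points did not, and black bars are list medians, which run from −1.05 for S phase and DNA replication to 1.01 for nuclear noncoding RNAs.

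After Hspb1, the inducible members of the HSP70 family rose most among the heat shock genes. Hspa1a (ENSMUSG00000091971, chromosome 17, 35188166 to 35191132, minus strand, build not given) rose from 0.507 ± 0.109 to 10.6 ± 0.711 FPKM, a log2 fold change of 4.34 ± 0.17 (edgeR adjusted p = 4.6e-07). Its near-identical neighbour Hspa1b (ENSMUSG00000090877, 35175412 to 35178214) rose from 2.18 ± 0.428 to 23.3 ± 2.23 FPKM (3.37 ± 0.16), and reads may have been split between both copies. Hspe1, the mitochondrial co-chaperonin, rose by a log2 fold change of 0.96 ± 0.08, and the co-chaperone Stip1 fell by 0.87 ± 0.08, from 271 ± 6.91 to 152 ± 4.72 FPKM. Bag3, a co-chaperone of HSP70, stood at 31.8 ± 3.13 and 30.03 ± 2.06 FPKM and did not pass (adjusted p = 0.369). Among 24 tested heat shock genes, 10 rose and 11 fell, the same numbers adjusted over the list alone (7 and 12 after GC correction). The list was not called (camera adjusted p = 0.331, direction higher). Its median of −0.16 (−0.26 to −0.12 with 1 library left out) and mean of 0.57 differ in sign.

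The metallothionein genes Mt1 and Mt2, whose small proteins bind copper and zinc, rose. Mt1 (ENSMUSG00000031765, chromosome 8, 94905710 to 94906955) rose from 168 ± 10.1 to 579 ± 71.2 FPKM, a log2 fold change of 1.75 ± 0.11, and Mt2 (ENSMUSG00000031762, 94899292 to 94900196) from 305 ± 7.07 to 739 ± 20.9 FPKM (1.24 ± 0.07). The copper chaperone Cox17 rose by 0.83 ± 0.10 and the zinc importer Slc39a1 fell by 0.58 ± 0.09. Ccs, which delivers copper to superoxide dismutase, stood at 28.8 ± 1.62 and 28.9 ± 2.88 FPKM (adjusted p = 0.820). Of 13 tested members of the metal response list, 6 rose and 2 fell, the same adjusted over the list alone (6 and 4 after GC correction), with a median of 0.08 that ran from 0.02 without control 2 to 0.26 without treated 3. Its call (camera adjusted p = 0.0466) was lost with an estimated correlation (adjusted p = 0.235). It was also lost without control 1, 2 or 3 or treated 1, at adjusted p values of 0.0825, 0.0501, 0.0735 and 0.0513. It held in 9 of 28 alternatives, with adjusted p from 0.000341 to 0.235.

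Genes tied to ferroptosis moved in both directions. Hmox1 (ENSMUSG00000005413, chromosome 8, 75820249 to 75827217), which breaks down haem and frees iron, rose from 51.3 ± 8.04 to 100.1 ± 7.24 FPKM (log2 fold change 0.92 ± 0.13). Ptgs2 (ENSMUSG00000032487, chromosome 1, 149975782 to 149983978), a cyclooxygenase often used as a marker of ferroptosis, rose from 12.6 ± 1.51 to 49.7 ± 6.95 FPKM (1.94 ± 0.12). The cystine transporter gene Slc7a11 (ENSMUSG00000027737, chromosome 3, 49846975 to 50398063) fell from 0.336 ± 0.0160 to 0.157 ± 0.00559 FPKM (−1.12 ± 0.17), and Gpx4 (ENSMUSG00000075706, chromosome 10, 79883000 to 79892273), which reduces lipid peroxides, from 558 ± 15.2 to 415 ± 41.8 FPKM (−0.46 ± 0.10). Acsl4, which supplies polyunsaturated acyl chains to phospholipids, rose by 0.99 ± 0.18, and the transferrin receptor gene Tfrc by 1.61 ± 0.27, but after GC correction these values were 0.23 and 0.79 (adjusted p = 0.0403 and 0.0105). Over all alternatives the adjusted p of Acsl4 ran from 7.9e-08 to 0.0403 and that of Tfrc from 1.9e-10 to 0.0319. Chac1, a glutathione-degrading enzyme, fell by 0.44 ± 0.09, and the ferritin heavy chain gene Fth1 stood at 808 ± 15.4 and 876 ± 61.4 FPKM (adjusted p = 0.442). Fth1 passed after GC correction at 0.29 and at a mean FPKM of at least 5 at 0.21, and with quantile normalization it passed the other way, at −0.26.

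Of 17 ferroptosis suppressors tested, 5 rose, among them Hspb1, and 9 fell, among them Dhodh (−1.16 ± 0.11), Nqo1 (−1.82 ± 0.20) and Gclm (−0.71 ± 0.09). These numbers were the same adjusted over the list alone (camera adjusted p = 0.458; mean 0.03, median −0.29, or −0.37 to −0.19 with 1 library left out). Of 15 drivers, 5 rose, including the polyamine enzyme gene Sat1 (1.14 ± 0.09), and 7 fell, including Cyb5r1 (−0.91 ± 0.08), the same adjusted over the list alone (camera adjusted p = 0.847; mean 0.13, median −0.12, or −0.22 to −0.11 with 1 library left out). Of 11 response markers, 5 rose, including Ddit4 (0.94 ± 0.13), and 4 fell, including Trib3 (−1.42 ± 0.09) and Sesn2 (−0.95 ± 0.10). Both numbers held when adjusted over the list alone (camera adjusted p = 0.654). Of 15 iron handling genes, 6 rose, including the mitochondrial iron importer Slc25a37 (1.06 ± 0.12), and 5 fell, including Aco1 (−0.82 ± 0.07). The same numbers were found adjusted over the list alone (camera adjusted p = 0.791; mean 0.24, median −0.04, which ran from −0.10 to 0.0025 with 1 library left out). Of 24 NRF2 targets, 9 rose and 10 fell, or 9 and 11 adjusted over the list alone (camera adjusted p = 0.478), with the glutathione transferase gene Gsta1 at 4.0 ± 0.24, G6pdx at −1.08 ± 0.07 and Txnrd1 at −0.84 ± 0.07. Of 25 glutathione and thioredoxin enzymes, 5 rose, including Gpx8 (2.14 ± 0.27) and Txnip (1.08 ± 0.08), and 11 fell, or 8 and 12 adjusted over the list alone (camera adjusted p = 0.565). Of 14 genes of superoxide and peroxide removal, 3 rose, including Sod1 (0.59 ± 0.08), and 6 fell, including Prdx6 (−0.49 ± 0.08), or 4 and 8 adjusted over the list alone (camera adjusted p = 0.598).

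**Figure D2:**
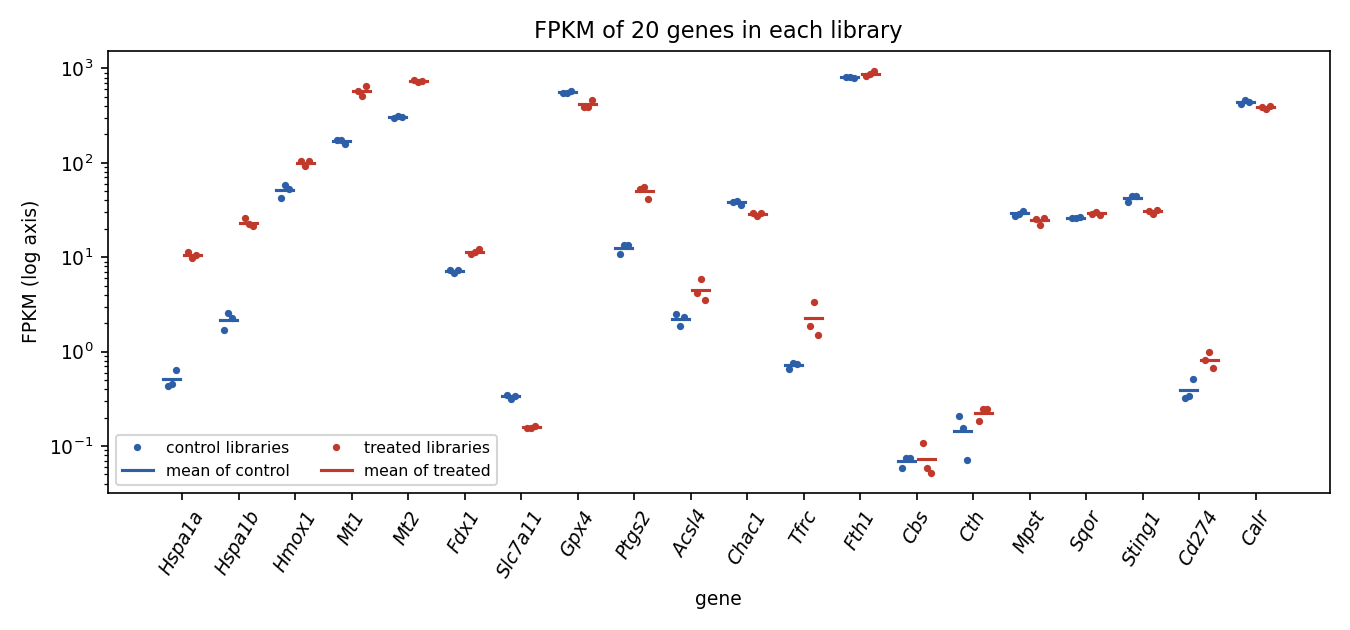
FPKM on a log axis of the 20 genes named whatever their result, in each of 3 control (blue) and 3 treated (red) libraries, with bars at the group means. Hspa1a and Hspa1b lie apart between groups, and Fth1, Cbs, Cth and Sqor did not pass the test.

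Of 14 genes of hydrogen sulfide metabolism, 0 rose and 10 fell, or 0 and 11 adjusted over the list alone (1 and 8 after GC correction). The list was called lower (camera adjusted p = 0.000153), a call lost with an estimated correlation (adjusted p = 0.227). It also holds genes of related amino acid metabolism, such as Mat2a, Ahcy, Mtr, Got1 and Got2. Its call is therefore not specific to enzymes that release or oxidise hydrogen sulfide. Mat2a (ENSMUSG00000053907, chromosome 6, 72409782 to 72416541), which makes S-adenosylmethionine, fell from 18.2 ± 4.45 to 3.68 ± 0.897 FPKM (−2.34 ± 0.19). Selenbp1, a methanethiol oxidase, fell from 19.8 ± 0.304 to 6.11 ± 0.302 FPKM (−1.73 ± 0.09), and Ahcy and Got2 fell by 0.89 ± 0.07 and 0.80 ± 0.09. Of the enzymes that release hydrogen sulfide, Cbs stood at 0.0691 ± 0.00892 and 0.0730 ± 0.0307 FPKM (adjusted p = 0.965), and Cth at 0.144 ± 0.0700 and 0.226 ± 0.0355 (adjusted p = 0.340). Mpst fell from 29.1 ± 1.83 to 24.6 ± 2.37 FPKM (−0.28 ± 0.10, adjusted p = 0.0388), a call lost in 13 alternatives (0.0512 to 0.170), among them without control 2, control 3, treated 1 or treated 2 and with the GC correction. Sqor, which oxidises sulfide in mitochondria, stood at 26.3 ± 0.440 and 29.1 ± 1.21 FPKM (adjusted p = 0.209), and passed after GC correction at 0.23, as it did with library totals only, with quantile normalization and at a mean FPKM of at least 5 (0.19 to 0.24).

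Of 33 targets of ATF4, which cells raise when amino acids run short, 5 rose and 23 fell, or 5 and 24 adjusted over the list alone, with a median of −1.01 (camera adjusted p = 6.9e-12; adjusted p = 0.249 with an estimated correlation). The one-carbon enzyme gene Mthfd2 fell from 39.4 ± 0.309 to 13.7 ± 0.484 FPKM (−1.56 ± 0.07), the amino acid transporter gene Slc7a5 from 103 ± 6.54 to 29.6 ± 1.16 (−1.84 ± 0.09) and the serine synthesis gene Psat1 from 134 ± 1.66 to 51.7 ± 2.22 (−1.42 ± 0.07). Ddit3 (CHOP), chosen after its value was seen, rose from 27.95 ± 0.572 to 69.5 ± 1.93 FPKM (1.28 ± 0.07). Of 23 genes of the unfolded protein response, 3 rose and 11 fell, among them Herpud1 (−1.06 ± 0.08) and Manf (−0.80 ± 0.08). These numbers were the same adjusted over the list alone (camera adjusted p = 0.0522). Hspa5, its main chaperone, stood at 111 ± 7.48 and 130.1 ± 20.05 FPKM (adjusted p = 0.155; called without treated 3, at 0.28 and 0.0265, and at a mean FPKM of at least 5, at 0.32 and 0.0377). The list was called lower without control 1, 2 or 3 or treated 1 or 2 (camera adjusted p = 0.0327 to 0.0455) and over every gene above 0 (0.00816 with edgeR, 0.0108 with limma). Of 15 cuproptosis genes, 3 rose, including Fdx1 (0.64 ± 0.09) and Dld (1.0 ± 0.18, or 0.31 after GC correction), and 4 fell, including Gcsh (−0.86 ± 0.08) and Dlst (−0.58 ± 0.08), the same adjusted over the list alone (2 and 6 after GC correction; camera adjusted p = 0.654).

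Of 27 hypoxia-linked genes, 20 rose and 2 fell, or 21 and 3 adjusted over the list alone, with a median of 0.98 (camera adjusted p = 1.1e-16; adjusted p = 0.0912 with an estimated correlation). The carbonic anhydrase gene Car9 rose from 19.8 ± 1.81 to 64.5 ± 4.99 FPKM (1.67 ± 0.10), the oxygen sensor gene Egln1 from 24.7 ± 0.312 to 65.3 ± 4.67 (1.37 ± 0.08) and Higd1a from 11.03 ± 0.816 to 31.1 ± 1.73 (1.46 ± 0.08). Of 22 glycolytic genes, 12 rose and 1 fell (the phosphofructokinase-2 gene Pfkfb3, chosen after its value was seen, at −1.35 ± 0.37, a call lost without both libraries numbered 2, at 0.0880), or 13 and 1 adjusted over the list alone (19 and 2 after GC correction; camera adjusted p = 0.000221; adjusted p = 0.406 with an estimated correlation). Among those that rose were Eno2 at 2.05 ± 0.13, Aldoa at 1.26 ± 0.09, the glucose transporter gene Slc2a1 at 1.15 ± 0.10 and Pdk1 at 1.13 ± 0.11. Slc2a1, Slc2a3, Hk2, Pgk1, Ldha, Pdk1, Pfkfb3 and Pfkfb4 were on both the hypoxia and the glycolysis list, so these calls are not independent. Eno1 stood at 841 ± 30.6 and 929 ± 59.4 FPKM (adjusted p = 0.305), and passed after GC correction at 0.32, with library totals only at 0.18, at a mean FPKM of at least 5 at 0.23 and with quantile normalization at −0.24.

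In the tricarboxylic acid cycle, 2 of 22 genes rose, including Sucla2 (1.43 ± 0.16), and 10 fell, including Ogdh (−1.29 ± 0.09), Cs (−0.71 ± 0.08) and Mdh2 (−0.70 ± 0.08), or 2 and 13 adjusted over the list alone (camera adjusted p = 0.0870; called lower over every gene above 0, at 0.00978 with edgeR and 0.00395 with limma). Of 38 nuclear genes of the respiratory chain, 10 rose, including Cox7c (1.26 ± 0.08) and Ndufa2 (1.0 ± 0.07), and 12 fell, including Atp5f1b (−0.69 ± 0.08) and Cycs (−0.61 ± 0.09), or 10 and 13 adjusted over the list alone (camera adjusted p = 0.847; mean 0.01, median −0.04, or −0.08 to −0.03 with 1 library left out). Of 13 mitochondrially encoded genes, 6 rose and 2 fell. Both numbers held when adjusted over the list alone (camera adjusted p = 0.476). Among them mt-Co1 rose from 3665 ± 745 to 8538 ± 2366 FPKM (1.19 ± 0.18). It was the most abundant gene of the treated libraries. The share of the mitochondrial chromosome was 2.54% against 1.51% of counts, and after GC correction 2 rose and 7 fell and the list was called lower, at a median of −0.79 (adjusted p = 0.0274). Without treated 1 and without the correction it was called higher, at a median of 0.71 (0.0385). Of 23 cholesterol synthesis genes, 5 rose, including Insig1 (1.05 ± 0.08), and 9 fell, including Mvk (−1.32 ± 0.08). The same numbers were found adjusted over the list alone (8 and 8 after GC correction; camera adjusted p = 0.476). Of 17 genes of fatty acid synthesis and desaturation, 5 rose, including Lpin1 (1.11 ± 0.09), and 6 fell, including Acaca (−1.15 ± 0.10) and Fasn (−0.92 ± 0.10). These numbers were the same adjusted over the list alone (camera adjusted p = 0.654).

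Of 44 S phase and DNA replication genes, 2 rose and 33 fell, or 3 and 33 adjusted over the list alone, with a median of −1.05 (camera adjusted p = 3.8e-26; adjusted p = 0.0285 with an estimated correlation). The replication licensing gene Cdc6 fell from 8.63 ± 0.669 to 2.05 ± 0.137 FPKM (−2.11 ± 0.11), Pole from 6.04 ± 0.264 to 1.67 ± 0.163 (−1.89 ± 0.09) and Lig1 from 50.9 ± 1.37 to 19.6 ± 0.712 (−1.41 ± 0.07), and Pcna stood at 82.7 ± 12.7 and 73.4 ± 10.3 (adjusted p = 0.170). Pcna passed after GC correction, at −0.64, and without both libraries numbered 2, at −0.39 (0.0157). Of 44 mitotic genes, 0 rose and 33 fell, or 2 and 34 adjusted over the list alone, with a median of −0.96 (camera adjusted p = 8.2e-25; adjusted p = 0.0912 with an estimated correlation). The mitotic transcription factor gene Foxm1 fell from 42.6 ± 1.48 to 12.7 ± 0.499 FPKM (−1.79 ± 0.08), with Pttg1 at −1.75 ± 0.08, Kif20a at −1.70 ± 0.08 and Bub1b at −1.46 ± 0.06. Of 30 DNA repair genes, 3 rose and 16 fell, or 3 and 17 adjusted over the list alone, with Fanca at −2.24 ± 0.12 and Msh6 at −1.09 ± 0.08 (camera adjusted p = 0.000156; adjusted p = 0.0912 with an estimated correlation).

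Of 32 ribosome biogenesis genes, 2 rose and 21 fell, or 2 and 24 adjusted over the list alone, with a median of −0.95 (camera adjusted p = 5.3e-18; adjusted p = 0.0285 with an estimated correlation). Rrp12 fell from 15.8 ± 1.23 to 3.51 ± 0.358 FPKM (−2.21 ± 0.11), Tcof1 from 29.3 ± 1.37 to 8.12 ± 0.666 (−1.89 ± 0.09) and the nucleolar gene Nolc1 from 61.7 ± 1.28 to 18.7 ± 1.24 (−1.76 ± 0.08). Myc stood at 72.6 ± 9.97 and 60.8 ± 4.06 FPKM (adjusted p = 0.0594; called without control 1, at −0.41 and 0.0137, and, at adjusted p values of 0.0263 to 0.0490, with DESeq2, with counts divided by 4, and in limma on TPM or at a mean FPKM of at least 5). Of 40 cytosolic ribosomal protein genes, 29 rose and 3 fell, or 30 and 3 adjusted over the list alone, with a median of 0.61 (camera adjusted p = 1.6e-10; adjusted p = 0.312 with an estimated correlation). Rpl37 rose from 84.0 ± 5.08 to 258 ± 3.21 FPKM (1.58 ± 0.07), Rps20 from 84.9 ± 4.47 to 232 ± 20.5 (1.42 ± 0.08) and Rps16 from 727 ± 21.8 to 1643 ± 97.8 (1.14 ± 0.08), and pseudogenes of this family can share their reads. In these same libraries the share of ribosomal RNA was 0.222% against 3.77%. Of 31 proteasome subunits, 9 rose, led by Psmc6 (2.77 ± 0.22), and 16 fell, led by Psmb2 (−0.94 ± 0.08), or 9 and 17 adjusted over the list alone (camera adjusted p = 0.524). Of 32 autophagy and lysosome genes, 22 rose and 1 fell, or 23 and 2 adjusted over the list alone (camera adjusted p = 4.3e-05; adjusted p = 0.227 with an estimated correlation), with the lysosomal enzyme genes Neu1 at 1.35 ± 0.12 and Ctsa at 0.91 ± 0.08.

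Among signals of immunogenic cell death, Anxa1, a ligand released by dying cells, rose from 12.9 ± 2.97 to 66.4 ± 17.8 FPKM (2.33 ± 0.19), and Hmgb1 fell from 7.42 ± 0.791 to 3.11 ± 0.378 (−1.29 ± 0.11). Calr, whose protein marks dying cells at the surface, fell from 443 ± 21.8 to 386 ± 16.3 FPKM (−0.23 ± 0.08, edgeR adjusted p = 0.0405), a call lost in 13 alternatives (0.0545 to 0.327), among them without control 2, control 3, treated 1 or treated 2 and with the GC correction. Of 11 members, 7 rose and 3 fell, the same adjusted over the list alone; Hspa1a and Hspa1b, also on the heat shock list, had the largest fold changes (camera adjusted p = 0.000847; adjusted p = 0.227 with an estimated correlation). Of 24 NF-kappaB inflammatory genes, 13 rose and 2 fell, the same adjusted over the list alone, with a median of 0.80 (camera adjusted p = 0.000194; adjusted p = 0.0912 with an estimated correlation). Nfkbia rose from 26.8 ± 0.821 to 79.8 ± 3.33 FPKM (1.54 ± 0.07), and the cytokine genes Csf2 and Cxcl1 by 1.81 ± 0.21 and 1.33 ± 0.15. Of 30 immediate early genes, 22 rose and 1 fell, or 23 and 2 adjusted over the list alone (camera adjusted p = 1.7e-08; adjusted p = 0.317 with an estimated correlation), with Egr1 rising from 45.5 ± 5.58 to 131 ± 4.26 FPKM (1.48 ± 0.11), Arc at 2.30 ± 0.19 and Klf6 at 1.57 ± 0.09.

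Most interferon response genes that changed were lower. Irf7 fell from 41.0 ± 0.458 to 19.7 ± 1.70 FPKM (−1.09 ± 0.09), Oas2 from 5.83 ± 0.590 to 2.37 ± 0.276 (−1.34 ± 0.13) and Stat2 from 9.28 ± 0.397 to 5.23 ± 0.279 (−0.86 ± 0.08), and Isg15 stood at 62.7 ± 4.47 and 59.6 ± 2.25 (adjusted p = 0.344). Of 36 members, 6 rose and 16 fell, or 7 and 16 adjusted over the list alone (camera adjusted p = 0.0522). Without control 1, control 2, treated 1 or treated 2 the list was called lower (0.0327 to 0.0476), as it was over every gene above 0 (0.00648 with edgeR, 0.0179 with limma). The adaptor gene Sting1 fell from 42.2 ± 3.42 to 30.5 ± 1.43 FPKM (−0.50 ± 0.09), and of 11 cGAS-STING genes 3 rose, including Ccl5 (1.34 ± 0.24), and 5 fell, including Irf3 (−0.49 ± 0.07), the same adjusted over the list alone (camera adjusted p = 0.670; mean 0.04, median −0.18, or −0.34 to −0.01 with 1 library left out). Of 19 genes of MHC class I presentation, 2 rose and 7 fell, including B2m (−0.38 ± 0.08) and Psmb10 (−0.54 ± 0.11). Both numbers held when adjusted over the list alone (camera adjusted p = 0.654). After GC correction the balance turned, with 8 raised and 3 lowered and a median of 0.18 against −0.02 (−0.07 to 0.02 with 1 library left out). H2-D1 stood at 574 ± 25.8 and 595 ± 35.4 FPKM (adjusted p = 0.899; it passed after GC correction, at 0.23, and at a mean FPKM of at least 5, at 0.14). Cd274, which encodes PD-L1, rose from 0.392 ± 0.106 to 0.822 ± 0.154 FPKM (1.03 ± 0.25, edgeR adjusted p = 0.00759), a call lost without both libraries numbered 2 (0.0734). Of 11 checkpoint ligands, 4 rose, including Pvr (1.13 ± 0.09) and Cd47 (0.67 ± 0.08), and 2 fell, Lgals9 (−1.0 ± 0.08) and Cd276 (−0.76 ± 0.09). The same numbers were found adjusted over the list alone (camera adjusted p = 0.654). Of 24 p53 targets, 11 rose, including Mdm2 (1.08 ± 0.10) and Plk2 (1.02 ± 0.08), and 7 fell, including Gtse1 (−1.40 ± 0.09), or 12 and 7 adjusted over the list alone (camera adjusted p = 0.654), and Cdkn1a stood at 183 ± 9.85 and 178 ± 12.3 FPKM (adjusted p = 0.507, or 0.0356 with quantile normalization, at −0.17). Of 28 genes of apoptosis and pyroptosis, 10 rose, including Casp6 (0.94 ± 0.10), and 8 fell, including Bak1 (−1.47 ± 0.07) and Birc5 (−1.32 ± 0.07). These numbers were the same adjusted over the list alone (camera adjusted p = 0.744; mean 0.15, median −0.08, or 0.06 without treated 3).

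Markers of other cell types were sparse. Of T cell and B cell markers 3 each were tested and 0 passed. S100a8 (1 of 3 neutrophil markers) and Itgax and Cd74 (2 of 3 natural killer and dendritic cell markers) rose, and Vwf (1 of 4 endothelial markers) rose by 0.96 ± 0.27. The S100a8 call was lost over every gene above 0 (0.0777) and without control 1, control 3 or any treated library (0.0588 to 0.0968) and its log2 fold change was 7.16 without control 2. The Itgax call was lost without treated 3 (0.0544). The Cd74 call was lost without control 2, control 3 or treated 3 (0.0512 to 0.0851) and with a replicate block (0.0651). Of 5 macrophage markers, 3 rose, including Cd68 (1.10 ± 0.09) and Cd14 (0.36 ± 0.09), and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0870, or 0.0345 after GC correction), and Lyz2 stood at 2.74 ± 0.272 and 2.70 ± 0.751 FPKM. Of 7 fibroblast markers, 1 rose, Dcn (2.24 ± 0.20), and 5 fell, including Acta2 (−2.58 ± 0.31), Col3a1 (−1.5 ± 0.09) and Col1a1 (−1.08 ± 0.08), the same adjusted over the list alone. That list was called lower (camera adjusted p = 0.0290), which was lost with an estimated correlation (adjusted p = 0.396), with the GC correction (0.0535), with counts divided by 4 (0.0555), without both libraries numbered 2 (0.0619) and in limma over every gene above 0 (0.0786). Its adjusted p ran from 0.0032 to 0.396 over the alternatives. Of 6 epithelial and colon markers, 3 rose, Krt19 (2.29 ± 0.33), Krt18 (1.28 ± 0.10) and Krt8 (0.67 ± 0.14), and Krt20 fell by 0.69 ± 0.07. Both numbers held when adjusted over the list alone (camera adjusted p = 0.148).

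Of 27 genes of extracellular matrix and adhesion, 11 rose, including Fn1 (0.96 ± 0.09), and 7 fell. The same numbers were found adjusted over the list alone (camera adjusted p = 0.654). Of 15 targets of YAP and TGF-beta, 7 rose, including Ccn1 (1.67 ± 0.16) and Ankrd1 (0.86 ± 0.07), and 3 fell. These numbers were the same adjusted over the list alone (camera adjusted p = 0.101, or 0.0213 after GC correction and 0.0430 without both libraries numbered 2). Of 12 nuclear noncoding RNAs, 8 rose, including Neat1 (2.42 ± 0.11), Snhg6 (2.22 ± 0.19) and Snhg12 (1.12 ± 0.11), and 3 fell, including Rn7sk (−2.76 ± 0.20), the same adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.227 with an estimated correlation). That call was also lost in edgeR on genes with a mean FPKM of at least 5 (0.517) and in each of the limma fits tried (0.0876 to 0.394). Rn7sk lacks a poly(A) tail, as does ribosomal RNA, whose share was 0.222% against 3.77%. Of 18 replication-dependent histone genes, 4 rose, including H1f2 (2.33 ± 0.16), and 3 fell, including H1f4 (−2.84 ± 0.27). Both numbers held when adjusted over the list alone (camera adjusted p = 0.598, direction higher; mean −0.11, median −0.06, or −0.24 to −0.02 with 1 library left out). This list was fixed as a check of RNA quality. Carry-over of RNA without poly(A) tails was not tested on it.

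The 10 raised genes that the rule took by fitted fold change were at 0 in all 3 control libraries, so only lower bounds can be given. The bounds lie below the fitted fold changes of Hspb1 and Hspa1a, which does not show that these genes rose less. Each bound sets the mean of the group above 0 against the floor. It leaves out the spread of that group, so single libraries can lie below it. Tcstv3 (ENSMUSG00000095821, chromosome 13, 120778414 to 120779714) reached 2.40 ± 0.356 FPKM in treated libraries, at least 12.3-fold higher against the floor, AF067061 1.17 ± 0.147 (at least 10.8-fold) and Mslnl 0.567 ± 0.118 (at least 9.80-fold). Hfm1, Pramel20, Pramel16, H2-Bl, Tdpoz8, Krt6a and Efcab6 followed, at least 4.66-fold to 9.29-fold higher, and several of these belong to multi-copy families whose reads can be shared. Among the lowered genes it took, Rn18s-rs5, a ribosomal RNA row (ENSMUSG00000119584, chromosome 17, 40157244 to 40159092) and the most abundant gene of control libraries, went from 19346 ± 822 to 1111 ± 60.7 FPKM (−4.16 ± 0.08). Lars2, which encodes mitochondrial leucyl-tRNA synthetase (chromosome 9, 123195992 to 123291731), fell by nearly the same amount, from 60.6 ± 3.05 to 3.43 ± 0.145 FPKM (−4.18 ± 0.09). Whether reads of ribosomal RNA were counted at Lars2 was not tested, so its fall is uncertain as that of the synthetase gene. Rmrp, an RNA without a poly(A) tail, fell from 6.84 ± 0.620 to 0.437 ± 0.352 FPKM (−3.87 ± 0.47, or −4.62 without treated 3). The histone gene H2ac15 fell by 4.0 ± 0.75 (−4.73 without treated 2) and Slc43a3 by 4.02 ± 0.80. Whether carry-over of RNA without a poly(A) tail bears on H2ac15 was not tested. Setmar and Izumo1 were at 0 in all treated libraries, at least 1.52-fold and 1.15-fold lower. BC048644, Papolb and Cmah fell from under 0.1 FPKM, and their calls were lost without treated 3 (BC048644, 0.0623), without control 3, treated 1 or treated 3 (Papolb, 0.0602 to 0.0651) and without control 2, control 3, treated 1 or treated 2 (Cmah, 0.0509 to 0.0812). The Papolb and Cmah calls were also lost over every gene above 0 (0.0505 and 0.0724), and that on Cmah without both libraries numbered 2 (0.0881). Among the fits with 1 library left out, the fold changes of these 3 genes moved most without treated 1 (BC048644, −5.24), treated 2 (Papolb, −7.56) and treated 3 (Cmah, −7.58).

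Among 2574 annotated terms, 44 were enriched among raised and 129 among lowered genes (1-sided Fisher exact test, Benjamini-Hochberg adjustment), or 68 and 180 with the GC correction. Cytoplasmic translation had 67 of 90 tested genes raised (adjusted p = 1.7e-20), with Rpl37, Rpl34 (1.64 ± 0.08) and Rps12 (1.68 ± 0.10) at the smallest p. The lysosome had 120 of 350 raised (0.000428), with Hyal1 at 2.06 ± 0.11, and cellular response to hypoxia 45 of 106 (0.00118), with Fam162a at 1.5 ± 0.07. DNA replication had 62 of 108 lowered (8.2e-09) and cell division 144 of 337 (4.3e-08). Aminoacyl-tRNA biosynthesis had 33 of 44 lowered (1.4e-08), with the isoleucyl- and methionyl-tRNA synthetase genes Iars1 at −1.49 ± 0.08 and Mars1 at −1.39 ± 0.08. Lars2, uncertain as above, is among the 33. RNA splicing had 119 of 274 lowered (3.7e-07), with Acin1 at −1.79 ± 0.08, Lsm2 at −1.99 ± 0.10 and Srrm2 at −1.55 ± 0.08.

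**Figure D3:**
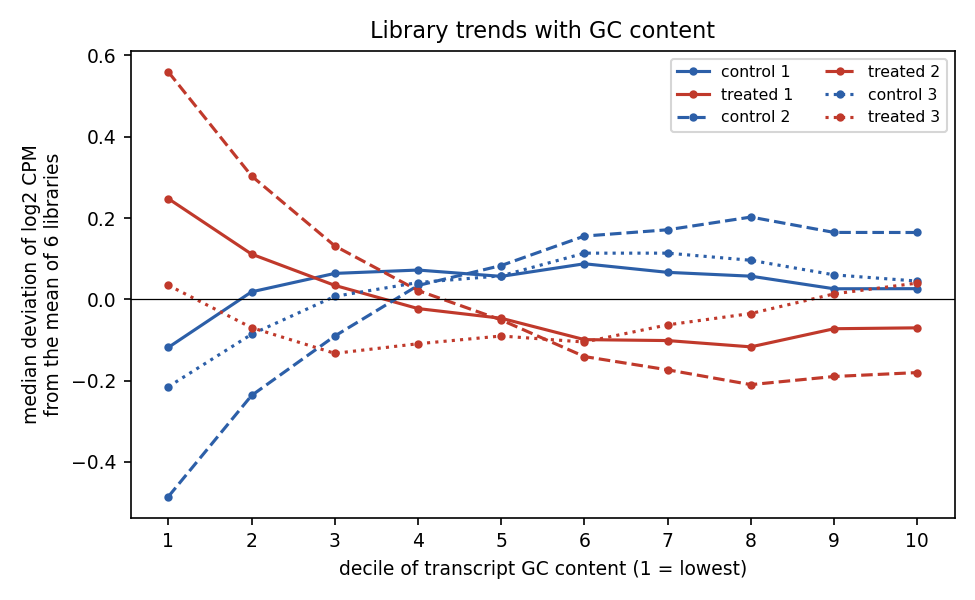
Median deviation of log2 CPM from the mean of the 6 libraries (vertical axis) in 10 bins of genes ordered by transcript GC content, for 3 control (blue) and 3 treated (red) libraries. Control 2 and treated 2 lie farthest apart in the lowest bin, at −0.49 and 0.56.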

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

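The tests on GC content, on RNA without poly(A) tails, on library depth and on genomic DNA were chosen after the results were seen, and the limits of both poly(A) tests were set again after a first outcome had been seen. The tests on pluripotent markers and on other splits of the libraries were set before their own outcomes were seen. The interval on the share of pluripotent markers was added after the outcome had been seen. The set of markers counted was changed once and then set back to all those listed.

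Genes left out of the test for low counts held a signal in treated libraries that control libraries lacked: 390 untested genes were at 0 in all 3 controls and above 0 in all 3 treated libraries, against 37 of the opposite kind (485 and 40 with tested genes included, 77 of the 485 with at least 12 estimated counts in each treated library). Library depth cannot account for this, since after thinning to 1 total the ratio was 8.82 (441 against 50), and genomic DNA cannot account for most of it, since 5 olfactory or vomeronasal receptor genes were among them, with an upper limit of 11.7, against 24.8 expected by number of genes and 53.3 weighted by transcript length. Receptor genes above 0 were still more frequent in treated libraries (40, 59 and 45) than in controls (25, 28 and 29), so a smaller share of genomic DNA may remain. Of 16 listed markers of pluripotent cells, 3 were above 0 in all treated libraries with a higher mean than in controls (Sox2 at 4.48 and 12.01 FPKM, Lefty1 at 3.39 and 5.3, Tfcp2l1 at 0.0265 and 0.0402), while Dppa4 (11.3 and 8.91) and Dppa2 (3.78 and 3.26) had lower means, Pou5f1, Dppa3 and Esrrb, at 0 in all controls, were above 0 in some but not all treated libraries (so 6 had a higher treated mean), and 8 were not among the genes listed, all of which were above 0 in some library. This share lay under the limit of 25% set beforehand, but its exact 95% interval of 4.05% to 45.6% reaches over that limit, so RNA from pluripotent cells stays open; reads shared between copies of gene families such as Tcstv3 and Pramel were not tested, and a response of the cells to the treatment stays open.

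Fold changes fell with GC content, from a median of 0.55 in the lowest GC decile to −0.14 in the highest. As the whole source of the called gene lists the trend was argued against, since 15 of 16 lists were called in the same direction after correction. Unequal recovery of GC-rich and GC-poor fragments between libraries is a candidate explanation for the trend itself: the lowest-minus-highest decile difference had a range of 0.745 within the treated libraries, 1.06 times the difference between group means (−0.35 in controls, 0.35 in treated; exact 2-sided permutation p = 0.1, the smallest possible). The libraries numbered 2 lay farthest out, at −0.65 and 0.74, and a change of the cells tied to GC content stays open.

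Ribosomal RNA took 3.77% of counts in control and 0.222% in treated libraries. Less ribosomal RNA alone in the cells was argued against, since 12 of 23 other tested RNAs without poly(A) tails were lowered past the threshold (exact 1-sided binomial p = 0.0027 against 23.5% of all genes; mitochondrial tRNAs, most of the list, are not independent of each other). Unequal carry-over of RNA without poly(A) tails may be involved: the median log2 fold change of these 23 was −1.08, but its limits of −1.73 and −0.09 keep this open. That median rests mostly on mitochondrial tRNAs. Rmrp, Rn7sk, Rn7s2 and Rn7s1, which are not mitochondrial, fell past the threshold (−3.87, −2.76, −2.68 and −2.67). Small noncoding RNAs took 0.0514% of counts in control and 0.00928% in treated libraries. Terc, which also lacks a tail, rose by 1.75, and lower levels of several such RNAs in treated cells were not tested.

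Of the 10 splits of the 6 libraries into 3 and 3, the split into control and treated gave 7548 changed genes and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.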

How the results depend on the processing

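The GC correction, library totals only, counts divided by 4, protein-coding genes only and the libraries numbered 2 left out were chosen after the data were seen; the other alternatives were set beforehand. The count of changed genes was 7683 with DESeq2, 7534 with library totals only, 6644 among protein-coding genes, 7637 with counts divided by 4, 6320 without both libraries numbered 2, and 6073 to 7264 with 1 library left out, against 7548. Raised and lowered genes numbered 4183 and 3351 with library totals only and 4194 and 3695 with the GC correction. No gene was called in opposite directions in any of these, and 4 were with the GC correction. Of 268 named genes, 267 kept their direction and side of the threshold with DESeq2, as did 247 of 266 with the GC correction. The shift of the median gene was 0.07 with TMM, 0.14 with library totals and 0.19 with upper-quartile scaling.

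With a mean FPKM of at least 5, where 6168 genes were tested, edgeR called 4410 (2217 raised, 2193 lowered, 734 at least 2-fold, 93 terms) and limma 4363 (1835 raised, 2528 lowered, 626 at least 2-fold, 80 terms). Among genes with a mean FPKM of at least 1, limma called 853 at least 2-fold with a pseudocount of 1, which shrinks the change of low genes, 1354 with 0.1 and 325 with 5. Of these, 474 were raised and 379 lowered with a pseudocount of 1, and 175 and 150 with 5, against 1600 and 840 with edgeR. It called 1118 on TPM, 839 after median-of-ratios scaling, 819 after quantile normalization, 852 without a trend, 842 with robust fitting and 852 over every gene above 0. The numbers of terms called were 97 with pseudocounts of 1 and 5, 100 with 0.1 and without a trend, 103 on TPM, 113 after median-of-ratios scaling and 106 with robust fitting, against 173. Over every gene above 0 they were 370 with limma and 411 with edgeR, and 71 when only genes changed at least 2-fold were counted. Except for the smaller number of genes under the stricter filter and the effect of the pseudocount, the cause was not tested. Camera called 2 lists with an estimated correlation and fry, which does not compare a list with other genes, called 29, against 16. DESeq2 gives no list test. Among the 16 lists, the call on immunogenic cell death was also lost after quantile normalization and in limma over every gene above 0 or a mean FPKM of at least 5 (adjusted p = 0.0718 to 0.11), and that on DNA repair at a mean FPKM of at least 5 (0.212 with edgeR, 0.296 with limma).

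Quantile normalization turned Fth1 to −0.26 (adjusted p = 0.00508, range over alternatives 0.00255 to 0.976) and Eno1 to −0.24 (0.00984, range 0.00011 to 0.735). The GC correction turned Vcam1 to −0.26 (adjusted p = 0.00482) and the mitochondrially encoded list to −0.79 (0.0274, range 0.0274 to 0.860). The cause was not tested. Papolb, Cmah, BC048644 and S100a8, all at low FPKM, lost their calls without single libraries; whether depth set this was not tested.

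With a replicate block, 6275 genes changed (3070 raised, 3205 lowered), 6229 of them shared with the fit without it. Deviations of same-numbered libraries correlated at 0.0399, −0.103 and 0.00645, so no shared deviation by number was seen. This cannot show whether the samples were prepared in pairs.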

Other observations

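The terms described here were picked after their tests were seen. Growth factor activity was enriched among raised genes, with 36 of 77 tested genes raised and 10 lowered (Fisher exact adjusted p = 0.000725, or 0.0168 after GC correction). Inhba, a subunit of activins, rose from 1.77 ± 0.0657 to 8.07 ± 0.949 FPKM (SD, n = 3), a log2 fold change of 2.15 ± 0.11 (SE), Il11 from 2.6 ± 0.468 to 15.1 ± 1.35 (2.50 ± 0.14) and Hbegf from 20.7 ± 1.57 to 61.1 ± 3.83 (1.52 ± 0.09). Circadian rhythm had 16 of 30 genes raised (adjusted p = 0.0194, or 0.0486 after GC correction), with the clock repressor gene Nr1d1 at 1.03 ± 0.09, Dbp at 0.87 ± 0.08 and Bhlhe41 at 1.13 ± 0.13. Structural constituents of the nuclear pore had 16 of 21 genes lowered and 0 raised (adjusted p = 0.000392), with Nup85 falling from 25.8 ± 0.0955 to 10.4 ± 0.496 FPKM (−1.35 ± 0.07) and Nutf2 from 47.6 ± 1.01 to 20.8 ± 0.93 (−1.23 ± 0.07). Neutrophil chemotaxis had 17 of 31 genes raised (adjusted p = 0.00985), with Spp1 at 1.88 ± 0.13 and Lgals3 at 0.85 ± 0.08.

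Zinc finger genes, a group chosen after the term tests were seen, had 121 of 319 raised and 24 lowered, with a median log2 fold change of 0.50. Their median GC content was 45.9%, against 51.3% for the 10080 genes of the GC trend, which had a mean log2 CPM above 2. After GC correction 110 zinc finger genes were raised and 27 lowered, with a median of 0.39. Of all 16212 rows tested without the correction, 3735 were raised and 3813 lowered (median 0.06). Of 15760 rows tested with it, 4194 were raised and 3695 lowered (median 0.08). The excess of raised zinc finger genes over all rows was thus smaller with the correction. Zfp97 rose from 0.236 ± 0.00712 to 1.87 ± 0.269 FPKM (2.93 ± 0.21, or 2.08 after GC correction).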
